A study of Homo sapiens with 6 samples.

How the data were processed

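RNA levels were measured on 6 oligonucleotide arrays of RT-112, a human bladder cancer cell line. Per the labels, the groups were cells given a scramble control siRNA, cells given siPPP2R2A_1 and cells given siPPP2R2A_2, here called siRNA 1 and siRNA 2, with 2 arrays (A and B) in each group. Per the labels' protocols, cells were plated at 50% confluence and transfected with 50 nM siRNA using Lipofectamine RNAiMAX, transfected again 24 h later, and harvested 24 h after that. The labels' protocols state that RNA was extracted with TRIzol and purified on RNeasy columns, and that biotin-labelled RNA was made with the MessageAmp Premier kit. The series' design text calls the arrays technical duplicates, so replicate variation here is that between these samples and not between separate experiments. Groups were taken from the sample titles. One title of siRNA 1 spells the gene differently, and it was assigned by its siRNA number.

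The deposited values are linear signal intensity per probe set, in one table of 54675 probe sets for the 6 arrays. Per the submitters' processing notes the tool was Affymetrix Expression Console. Its version and its algorithm are not given in the sources used here. In the table, the mean signal after trimming 2% from each tail lay between 500.067 and 500.07 on every array, and the array medians between 69.3 and 76.2. No detection calls came with the values.

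Values were used as deposited, on the scale log2(signal + 1). Gene symbols came from the platform's probe table and were looked up by Entrez identifier in a RefSeq gene table of the GRCh38 assembly, used for names alone. Of the probe sets with 1 symbol 41043 matched and 54 did not, and 0 symbols changed. Of all probe sets, 62 were controls, 41097 carried exactly 1 symbol, 1801 carried several and 11777 carried none. Each of the 19775 genes was represented by its probe set with the highest mean over the 6 arrays. A gene was tested when that probe set was above the array's 50th percentile on at least 2 arrays, which left 12735 genes and removed 7040. Of the probe sets tested, 4381 (34.4%) are of the types that can also bind related transcripts. Probe sets with several symbols and with none were left out of the main comparisons because they name no single gene.

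Groups were compared with limma 3.58.1 (lmFit with a coefficient per group over all 6 arrays, then eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05 and a change of at least 1.5-fold. The fit had 3 residual degrees of freedom and 1.72 prior degrees of freedom. The contrasts were siRNA 1 minus scramble, siRNA 2 minus scramble, their mean, and siRNA 1 minus siRNA 2. Levels are given as the mean ± SD of the 2 signals of a group. Gene lists with at least 5 tested members were compared with all other genes by limma's camera at a preset correlation of 0.01 between genes, with adjustment over lists, and again with an estimated correlation. Counts of called members are given over all genes tested and adjusted over the list alone. For the comparisons that share the scramble arrays, 100 simulations were drawn in which all 6 arrays, scramble included, were simulated without group differences. Correlations used each gene's residual variance. Call counts used limma's moderated variance, which draws each gene's variance towards a common value. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

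The groups, the tests, the gene lists, the rule for named genes and nearly all other settings were fixed before the data were examined. By that rule the text names PPP2R2A and the other subunits of its phosphatase, the 10 genes with the largest mean rise and the 10 with the largest mean fall among genes called with both siRNAs and with every knockdown array on the same side of both scramble arrays, the 5 genes with the largest difference in each direction between the siRNAs, and up to 4 members of each list called with both siRNAs. All other genes named, whether called or not, were chosen after their values were seen.

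The limma fit was tested on simulated data with 200 changed genes among 12735. Another 36 genes, members of the unfolded protein response and ATF4 list, were raised by a log2 change of 0.4 with both siRNAs. They are left out of the counts below. Camera called that list at an adjusted p = 6.17e-31 and 2.51e-32 with siRNA 1 and siRNA 2. With an estimated correlation camera gave an adjusted p = 0.0406 and 0.0380. For siRNA 1 against scramble it recovered 10.4% of genes changed 1.5-fold, 55.2% of those changed 2-fold and 84.8% of those changed 4-fold, with 1 unchanged gene called. For siRNA 2 against scramble the shares were 11.9%, 52.2% and 84.8%, with 5 unchanged genes called. For the contrast between the siRNAs, in which no simulated gene differed, it called 0.

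The other settings run were quantile normalization, centring each array on its median, the replicate letter as a block, an intensity trend in the prior variance of eBayes, no filter on dim probe sets, a filter at the 75th percentile, the mean of a gene's probe sets, no fold limit, a 2-fold limit, all probe sets, a pseudocount of 16, only the 4 arrays of the groups compared, leaving out each array in turn, duplicates averaged first, split scramble arrays, the other PPP2R2A probe sets, and for lists an estimated correlation and limma's fry. The intensity trend combined with leaving out each array was added after seeing the data.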

Results

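Transcript levels were measured in RT-112 bladder cancer cells after silencing of PPP2R2A, which encodes a B-type regulatory subunit of protein phosphatase 2A (PP2A). Cells received a scramble siRNA, siRNA 1 or siRNA 2 against PPP2R2A, with 2 arrays per group and 6 in all. The arrays were technical duplicates, so every p-value of a single gene measures only the spread between these samples. A camera p-value sets the genes of a list against all other genes. Its size depends on the correlation assumed between genes and on whether that is preset or estimated. Neither kind of p-value measures variation between separate experiments. For NF-kappaB targets with siRNA 1 the estimated correlation was -0.0128, below the preset 0.01. The unadjusted camera p still rose from 0.00457 to 0.0535. A call lost with an estimated correlation is therefore not by itself a sign that the genes of the list are correlated. The small number of arrays limits the precision. Duplicates correlated at 0.979 to 0.980 over the tested genes, and arrays of different groups at 0.970 to 0.978. The ratio of 3' to 5' signal of ACTB, a sign of RNA integrity and labelling, averaged 5.68 with scramble, 7.17 with siRNA 1 and 9.92 with siRNA 2, where the duplicates stood at 7.47 and 12.4. The same ratio for GAPDH averaged 1.00, 1.01 and 0.972.

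On its brightest probe set PPP2R2A was lower on every knockdown array. The signals were 1381 and 1589 with scramble, 336 and 397 with siRNA 1, and 510 and 533 with siRNA 2. They left 24.7% of the scramble level with siRNA 1 (log2 change -2.02, limma adjusted p = 0.0403) and 35.2% with siRNA 2 (log2 change -1.51, adjusted p = 0.0461). The mean of both siRNAs lay at a log2 change of -1.76 (adjusted p = 0.0345). A second probe set, 228013_at, read 440 ± 7.90 with scramble, 90.6 ± 25.8 with siRNA 1 and 108 ± 4.82 with siRNA 2 (SD, n = 2). A further one, 236492_at, retained 95.7% and 77.9% of its scramble signal, and 1 siRNA 1 array read 334 on it, above both scramble arrays (287 and 281). The difference between the siRNAs was not called (log2 difference -0.51, adjusted p = 0.158). Without any 1 of the 6 arrays the mean log2 change lay between -1.86 and -1.66, with adjusted p from 0.129 to 0.200.

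**Figure D1:**
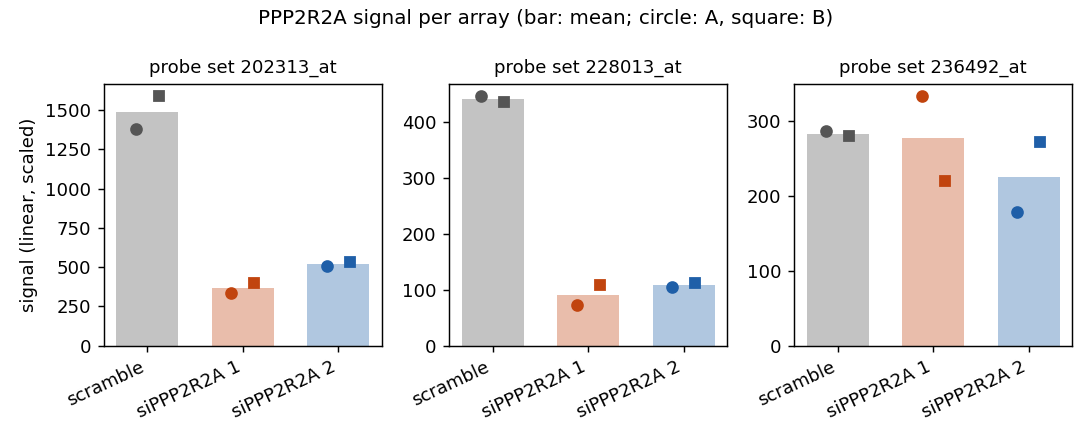
Linear scaled signal of the 3 PPP2R2A probe sets above the filter, per array (circles A, squares B), with bars for group means. On 202313_at the scramble arrays sit at 1381 and 1589, and the 4 knockdown arrays between 336 and 533.

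Among the other PP2A subunits, PPP2R1B, the beta isoform of the scaffold subunit, rose with siRNA 2 from 839 ± 6.70 to 1997 ± 51.9 (log2 change 1.25, adjusted p = 0.0461). With siRNA 1 it stood at 1479.8 ± 203 (log2 change 0.81, adjusted p = 0.0807), and the siRNAs did not differ for this gene by the test (adjusted p = 0.172). With an intensity trend limma called PPP2R1B higher with both siRNAs (adjusted p = 0.00183 and 0.000163). The mean of its probe sets gave log2 changes of 0.27 and 0.20, neither called. The other 16 subunits, among them the catalytic PPP2CA and PPP2CB and the related PPP2R2B, PPP2R2C and PPP2R2D, were not called, with log2 changes from -0.25 to 0.37 with siRNA 1 and from -0.32 to 0.67 with siRNA 2. Of these, PPP2R1A alone was called by limma with an intensity trend, higher with siRNA 2 (log2 change 0.67, adjusted p = 0.0242). As lists, the subunits (camera adjusted p = 0.800 and 0.577) and the PP2A regulators (0.918 and 0.552) were not called. BOD1, a regulator that inhibits a PP2A complex, was the 1 of 14 regulators called, with both siRNAs.

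The comparison of siRNA 1 with scramble asks which transcripts changed with that siRNA. MMGT1, a subunit of a membrane protein insertion complex, fell from 2299.8 ± 62.9 to 588 ± 15.4 (log2 change -1.97, adjusted p = 0.0368, n = 2 per group). SKAP2, a kinase-associated adaptor, fell from 3387 ± 53.9 to 1194 ± 24.97, and RAB21, a GTPase of endosomes, from 1871 ± 31.5 to 799.9 ± 29.2. HMGA2, a chromatin architectural protein (log2 change 1.25, adjusted p = 0.0430), and CLDN1, a tight junction protein (log2 change 1.02, adjusted p = 0.0489), rose. In all, limma called 50 genes, 27 higher and 23 lower, and 2063 genes had an unadjusted p under 0.05. Without each of the 6 arrays in turn limma called 0 (1464 to 1937 at an unadjusted p under 0.05). With an intensity trend in the prior variance it called 299 genes (175 higher, 124 lower), including 46 of the 50, and centring arrays on their medians gave 11 (5 higher, 6 lower).

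With siRNA 1 the interferon response genes were higher as a group, 41 of 42 tested members lying above 0 with a median log2 change of 0.48 (camera adjusted p = 1.00e-15). With an estimated correlation the call was lost (adjusted p = 0.419 with an estimated correlation). IFI44L alone was called over all genes, and 15 members rose when adjusted over the list alone. The chemokine CXCL10 stood at 1.42 and the antiviral GTPase MX1 at 0.79, neither called over all genes. The unfolded protein response and ATF4 targets were also higher (30 of 37 above 0, median 0.31, adjusted p = 4.07e-07, and adjusted p = 0.419 with an estimated correlation), with SEL1L called over all genes and 11 members higher adjusted over the list alone. TGF-beta targets were lower (n = 23 genes, median -0.16, adjusted p = 0.00158, and adjusted p = 0.680 with an estimated correlation), with 0 called by limma over all genes, 3 lower adjusted over the list alone, 3 lower with an intensity trend, and 7 lower and 1 higher at an unadjusted p under 0.05. The basal and squamous genes (median -0.18, adjusted p = 0.0426) and the actin and SRF targets (median -0.10, adjusted p = 0.0471) were lower and the NF-kappaB targets higher (median 0.15, adjusted p = 0.0426). With an estimated correlation these gave an adjusted p = 0.715, 0.715 and 0.551. Adjusted over the list alone, 3 basal and squamous genes, 1 actin or SRF target and 0 NF-kappaB targets were called by limma, against 0 of each over all genes. At an unadjusted p under 0.05 the counts were 7 lower and 1 higher, 5 lower and 1 higher, and 6 higher, and with an intensity trend 3 lower, 1 lower and 2 higher. Of 13 other settings, the call was lost in 7 for basal and squamous genes, 10 for actin and SRF targets, 6 for NF-kappaB targets and 1 for TGF-beta targets (without scramble A, adjusted p = 0.0766). The basal and squamous call ended without scramble A (median -0.15, adjusted p = 0.156), without siRNA 1 array A (-0.21, adjusted p = 0.0701) and without siRNA 1 array B (-0.0375, adjusted p = 0.122). The ACTB 3' to 5' ratio was also higher with siRNA 1 (7.17 against 5.68).

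The comparison of siRNA 2 with scramble asks the same of the other siRNA. NETO2, an auxiliary subunit of kainate receptors, fell from 3332 ± 90.8 to 1229.6 ± 20.1 (log2 change -1.44, adjusted p = 0.0385, n = 2 per group), and MREG, melanoregulin, from 2269 ± 162 to 712 ± 3.73 (log2 change -1.67). The epithelial defensin DEFB1 (log2 change -1.73, adjusted p = 0.0385), the cornified envelope gene SPRR1B (-1.61, adjusted p = 0.0461) and the TGF-beta receptor gene TGFBR2 (-1.09, adjusted p = 0.0461) also fell. The polyamine synthesis gene ODC1 (log2 change 1.21) and the anti-apoptotic gene MCL1 (1.01) rose, both at an adjusted p = 0.0461. In all, limma called 76 genes, 56 higher and 20 lower, and 2644 had an unadjusted p under 0.05. Centring arrays on their medians left 1 call, which was higher, and 0 lower. Without each of the 6 arrays in turn limma called 0 (1922 to 2416 at an unadjusted p under 0.05), and with an intensity trend it called 472 (292 higher, 180 lower), including 71 of the 76.

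With siRNA 2 the unfolded protein response and ATF4 targets were higher, 34 of 37 lying above 0 with a median log2 change of 0.40 (camera adjusted p = 2.93e-09, and adjusted p = 0.333 with an estimated correlation). The asparagine synthetase gene ASNS (1.19), the glutathione-degrading CHAC1 (1.16), SEL1L (1.06) and the pseudokinase TRIB3 (0.92) rose over all genes, and 12 members rose adjusted over the list alone. The mean of the probe sets of ASNS gave 0.21, not called. Basal and squamous genes were lower, with 1 of 23 above 0 and a median of -0.44 (adjusted p = 4.10e-08, and adjusted p = 0.333 with an estimated correlation). SPRR1B was the 1 member called over all genes and 7 fell adjusted over the list alone. The calprotectin gene S100A8 stood at -1.98 and the mucosal keratin KRT13 at -0.67, neither called over all genes. Urothelial luminal genes were lower (n = 24 genes, median -0.20, adjusted p = 0.00147, and adjusted p = 0.333 with an estimated correlation), with 0 called by limma over all genes, 2 lower adjusted over the list alone, 3 lower with an intensity trend, and 9 lower and 1 higher at an unadjusted p under 0.05. Ribosome biogenesis and MYC targets were lower (median -0.15) although ODC1, a member, rose, and histone genes were higher (median 0.26), each at an adjusted p = 0.0351 and an adjusted p = 0.780 with an estimated correlation. Adjusted over the list alone 1 ribosome or MYC target and 2 histones rose and 0 of each fell, against 1 and 0 higher over all genes by limma. At an unadjusted p under 0.05 the counts were 5 lower and 2 higher for ribosome and MYC targets and 4 higher for histones, and with an intensity trend 1 higher and 2 higher. Of 13 other settings, the call was lost in 8 for ribosome and MYC targets and 4 for histones. Without siRNA 2 array A the ribosome and MYC median was -0.0943. Interferon genes had a median of 0.08 and were not called as a list (adjusted p = 0.138), while IFI44L and IFI6 rose over all genes and 9 rose and 3 fell adjusted over the list alone. The ACTB 3' to 5' ratio was highest in this group (9.92 against 5.68 with scramble).

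**Figure D2:**
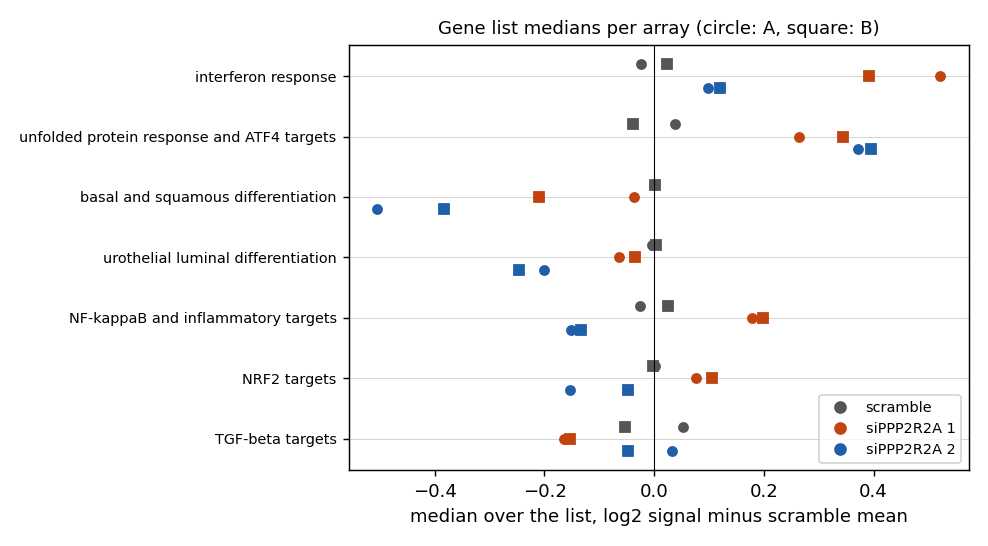
Median over each of 7 gene lists of the log2 signal minus the scramble mean, per array (circles A, squares B; colours give the group). The interferon list lies at 0.52 and 0.39 on the siRNA 1 arrays and at 0.10 and 0.12 on the siRNA 2 arrays.

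Genes called with both siRNAs are those whose change both PPP2R2A siRNAs share, each set against the same scramble siRNA. IFI44L, an interferon-induced gene, rose from 86.6 ± 8.82 to 533 ± 55.5 with siRNA 1 and 558 ± 27.4 with siRNA 2 (log2 changes 2.61 and 2.68, adjusted p = 0.0368 and 0.0385, n = 2 per group). MET, the hepatocyte growth factor receptor, rose from 3004 ± 27.2 to 7223 ± 101 and 7263 ± 483, and CCND3, cyclin D3, from 879.5 ± 62.0 to 1859 ± 115 and 2061 ± 89.3. BANF1, a protein of nuclear envelope assembly, rose by log2 changes of 1.20 and 1.20, the mitochondrial phosphatase PTPMT1 by 1.49 and 1.36, the Golgi glycosyltransferase MGAT4A by 1.47 and 1.16, the phospholipase PLCB1 by 1.36 and 1.75, and SUSD1 by 1.74 and 1.40. ALPP, placental alkaline phosphatase, went from 9.75 ± 4.62, below the filter level, to 160 ± 48.5 and 212 ± 20.03, and its probe set may also bind closely related alkaline phosphatase transcripts. LRIG1, a negative regulator of receptor tyrosine kinases, rose from a dim 15.6 ± 1.54 to 91.7 ± 16.8 and 48.9 ± 0.386. Both siRNA 2 arrays (48.6 and 49.1), like both scramble arrays, read below the filter level, so its change with siRNA 2 rests on the background level. With an intensity trend limma did not call LRIG1 (adjusted p = 0.0778 and 0.203).

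From the fixed lists, SEL1L, part of endoplasmic reticulum-associated degradation, rose with both siRNAs (log2 changes 1.04 and 1.06), as did PTPN14, a phosphatase that binds YAP (1.20 and 0.96), and BOD1 (1.09 and 1.05). Of all genes called with both siRNAs, 19 rose and PPP2R2A alone fell, 20 in total, and 0 went in opposite directions by limma. Besides those named, CYP27C1, TAPT1, CALU, C12orf57, NRBF2 and STMN1 rose, named after their values were seen. The 19 risers had median log2 changes of 1.20 and 1.20, and on all 4 knockdown arrays each of the 20 genes lay on the same side of both scramble arrays. That separation adds no support of its own, as the genes were selected by calls against these scramble arrays with both siRNAs. Centring arrays on their medians left 1 shared call, which was higher, so that PPP2R2A was not called with both. With a pseudocount of 16 LRIG1 stood at 1.04 with siRNA 2. Of the 20 genes, 9, PPP2R2A included, had other probe sets above the filter, 20 in total. Of these probe sets, 19 moved in the gene's direction with both siRNAs, at least 1 in each of the 9 genes. The exception was 1 for MGAT4A (0.54 with siRNA 1 and -0.14 with siRNA 2). Sizes varied, with 1 probe set of SEL1L at 1.20 and 1.16 and another at 0.06 and 0.09. Taking the mean of a gene's probe sets turned CCND3 to -0.12 and -0.08 and lowered MET to 0.55 and 0.25, MGAT4A to 0.86 and 0.59 and PTPN14 to 0.62 and 0.65, and limma then called 0 genes with both siRNAs (565 at an unadjusted p under 0.05 with the same sign). Without each of the 6 arrays in turn it called 0 (671 to 803 at an unadjusted p under 0.05), and with an intensity trend 121 (109 higher, 12 lower), including 19 of the 20.

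**Figure D3:**
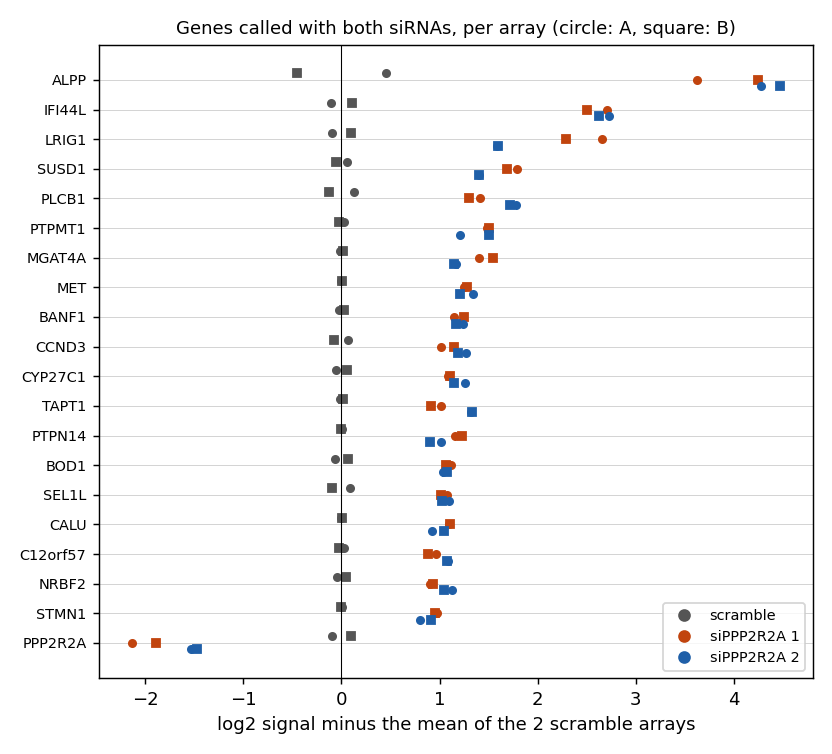
Log2 signal minus the mean of the 2 scramble arrays for the 20 genes called with both siRNAs, per array (circles A, squares B; colours give the group). For 19 genes the 4 knockdown arrays lie above both scramble arrays, and for PPP2R2A below them.

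Independent lists of these sizes would share 0.119 genes higher and 0.0361 lower. In 100 simulations that drew all arrays anew without group differences, at most 0 genes were called with both. The simulated noise for these calls was limma's moderated estimate of the spread between duplicates, which leaves out any deviation common to both scramble arrays. Log2 changes with the siRNAs correlated at a Pearson r of 0.496 and a Spearman rho of 0.450 across 12735 genes, which are not independent replicates. Simulated unchanged groups that share simulated scramble arrays gave 0.502 and 0.445 on average. The covariance was 0.0765 against a simulated 0.0503, a difference of 0.0262. With scramble A used for one siRNA and B for the other the Pearson r was 0.109, and 0.146 the other way round. Those splits leave 1 scramble array per siRNA, and with 2 in all no split can keep 2 for each siRNA. The split correlations cover all 12735 genes and do not test the genes called with both siRNAs. For those calls, the simulated spread between duplicates gave at most 0, which argues against noise of single scramble arrays as their source. A deviation common to both scramble arrays is met by neither the splits nor the simulations. Part of the shared calls may therefore come from such a deviation.

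**Figure D4:**
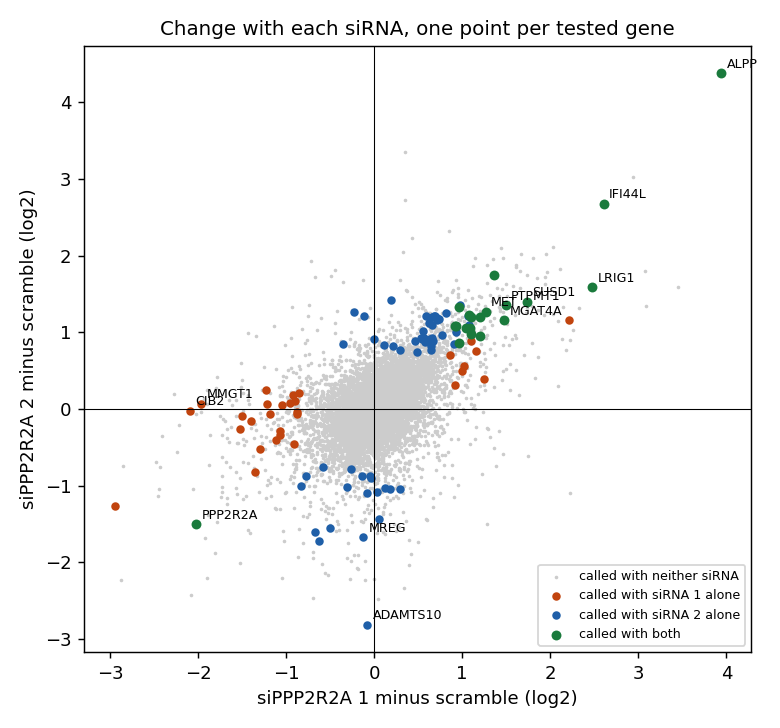
Log2 change with siRNA 1 (horizontal) against siRNA 2 (vertical), 1 point for each of 12735 tested genes, coloured by the comparisons in which it was called. The 20 genes called with both siRNAs hold 19 in the upper right and PPP2R2A in the lower left.

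The contrast of the siRNAs asks which changes differ between them. MMGT1 (log2 difference siRNA 1 minus siRNA 2 of -2.03, adjusted p = 0.0418), RAB21 (-1.48), SKAP2 (-1.42), the calcium-binding CIB2 (-2.07) and C12orf75 (-1.64) were lower with siRNA 1. NETO2 (1.49, adjusted p = 0.0418), MREG (1.55), the protease gene ADAMTS10 (2.73), the cytochrome P450 gene CYP4B1 (1.33) and IL13RA1, a receptor for interleukin 13 (1.23), were higher with siRNA 1. ADAMTS10 with siRNA 2 (19.3 ± 6.47) and CIB2 with siRNA 1 (21.4 ± 1.42) read below the filter level of 69.3 to 76.2, so the sizes of these differences rest on the background level. SKAP2 read 1194 ± 24.97 with siRNA 1 and 3196 ± 115 with siRNA 2, against 3387 ± 53.9 with scramble. Limma called 27 genes, 11 higher and 16 lower with siRNA 1, against 12 (6 higher, 6 lower) after quantile normalization and 0 after centring arrays on their medians (1689 at an unadjusted p under 0.05). Of the 11, 8 were called lower with siRNA 2 against scramble and 0 higher with siRNA 1, and of the 16, 10 were called lower with siRNA 1 and 2 higher with siRNA 2. The unadjusted p was under 0.05 for 2381 genes. Without each of the 6 arrays in turn limma called 0 (1599 to 2162 at an unadjusted p under 0.05), and with an intensity trend 362 (207 higher, 155 lower), including 24 of the 27. The mean of the gene's probe sets gave 0.57 for IL13RA1, 0.95 for NETO2 and -0.63 for SKAP2, none called.

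As lists, interferon response genes (median difference 0.21, adjusted p = 3.28e-05), NF-kappaB targets (0.32, adjusted p = 0.000336), NRF2 targets (0.26, adjusted p = 0.000203), urothelial luminal genes (0.19, adjusted p = 0.000455) and basal and squamous genes (0.33, adjusted p = 0.000455) were higher with siRNA 1 than with siRNA 2. With an estimated correlation these gave an adjusted p = 0.509, 0.407, 0.509, 0.407 and 0.509. The NRF2 call was also lost with the mean of probe sets (0.12, adjusted p = 0.226). Over 13 other settings the median differences, in the same order, ran from 0.13 to 0.30, 0.12 to 0.43, 0.12 to 0.32, 0.17 to 0.20 and 0.20 to 0.38. With an intensity trend the epithelial junctions (0.09, adjusted p = 0.0387) were called higher too, and the histones (-0.17, adjusted p = 0.0493) lower. Over all genes limma called 0 members of each, and adjusted over the list alone 7, 4, 4, 1 and 4 were higher. With an intensity trend 7, 4, 4, 2 and 5 were higher, and at an unadjusted p under 0.05 the higher members numbered 19, 9, 10, 6 and 9. MX1 stood at 0.79 with siRNA 1 and -0.88 with siRNA 2, and CXCL10 at 1.42 and -0.29 (adjusted p of the difference 0.0575), while XAF1 stood at 1.51 and 1.48. The unfolded protein response and ATF4 targets did not differ by the test (median difference -0.06, adjusted p = 0.252). The ACTB ratio was 7.17 with siRNA 1 and 9.92 with siRNA 2.

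Of 39 lists tested, 2 were called with both siRNAs in the same direction. These were unfolded protein response and ATF4 targets (higher) and basal and squamous genes (lower). A further 4 were called with siRNA 1 alone and 3 with siRNA 2 alone. The TGF-beta, actin and SRF, ribosome and MYC, and histone lists among them were not called in the difference. With the other siRNA their medians were -0.10 (camera adjusted p = 0.148), -0.02 (0.985), -0.07 (0.0723) and 0.22 (0.800). Of 13 other settings, 4 called the histone difference. The basal and squamous list was no longer called with both under quantile normalization, without a filter, at the 75th percentile or with the mean of probe sets, because its call with siRNA 1 was lost. With an intensity trend 3 lists were called with both, the ribosome biogenesis and MYC targets being added as lower (adjusted p = 0.0370 and 0.0162). In that fit NRF2 targets were also called, higher with siRNA 1 (adjusted p = 0.0219) and lower with siRNA 2 (adjusted p = 0.0335), and G1/S genes were lower with siRNA 1 (adjusted p = 0.0219). With an estimated correlation 0 lists were called by camera, and limma's fry called 2 with both, the unfolded protein response and ATF4 targets higher and G1/S genes lower. The other 30 were called with neither, with medians from -0.26 to 0.15 with siRNA 1 and from -0.31 to 0.15 with siRNA 2, and a lowest adjusted p of 0.0567 and 0.107. They include mitotic (G2/M) genes, with medians of -0.00 and -0.04, G1/S genes (-0.06 and -0.03), homologous recombination genes (-0.05 and -0.05) and p53 targets (0.03 and -0.09). In these 4 lists 0 of 138 members were called by limma over all genes, 2 with each siRNA with an intensity trend, and 19 and 20 at an unadjusted p under 0.05. Of 13 other settings, 1 called the homologous recombination list lower with siRNA 1, and 1 called the fatty acid synthesis list with siRNA 2. For p53 targets with siRNA 1 the median and mean lay above 0 and the test pointed lower, and in 16 of 78 combinations of list and siRNA the median, mean and test differed in sign, 0 of them called.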

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

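The tests of shared noise, of scaling, of transcripts lowered by the received siRNA and of proportional PPP2R2A loss, and the 3' bias test of the interferon list, were chosen only after the result was seen. Intervals given are bootstrap intervals over genes and treat genes as independent, except that the interval of the depletion ratio comes from the limma error of PPP2R2A, and intervals of values scaled by that ratio include its spread. The ratio was taken on probe set 202313_at alone.

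Several genes differed between the siRNAs by limma's contrast of one against the other, which is why they are listed here. Log2 differences, siRNA 1 minus siRNA 2, were 2.73 for ADAMTS10, 1.55 for MREG, 1.49 for NETO2, 1.33 for CYP4B1 and 1.23 for IL13RA1. They were -2.07 for CIB2, -2.03 for MMGT1, -1.64 for C12orf75, -1.48 for RAB21 and -1.42 for SKAP2. ADAMTS10 with siRNA 2 (19.3) and CIB2 with siRNA 1 (21.4) lie below the filter level of 69.3 to 76.2, so their sizes rest on the background level. By camera, list medians also differed between the siRNAs, by 0.32 for NF-kappaB targets, 0.26 for NRF2 targets, 0.19 for urothelial luminal genes and 0.33 for basal and squamous genes, and by 0.21 for interferon genes. With an estimated correlation these gave an adjusted p = 0.407, 0.509, 0.407, 0.509 and 0.509, and the NRF2 difference was 0.12 and not called with the mean of probe sets. The ACTB 3' to 5' ratio, measured on control probe sets outside the comparisons, averaged 7.17 with siRNA 1 and 9.92 with siRNA 2, above the 5.68 with scramble.

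Of the genes called with both siRNAs, 19 of 20 were lower in scramble, as were 92.9% of 14 after quantile normalization. Among genes above the 75th percentile the share was 91.2% of 114. These shares argue against scaling and skewed noise of dim probe sets as the whole cause. Centring arrays on the medians of all probe sets left 1 shared call. In a separate centring on the medians of the tested genes, the risers' medians moved from 1.20 to 1.16 with each siRNA. There the risers' adjusted p by limma reached up to 0.0523. The risers differed little between the siRNA 2 duplicates, whose ACTB ratios were 7.47 and 12.4 (median -0.0235, interval -0.08 to 0.02, against a change of 1.20), which argues against 3' bias. Each PPP2R2A siRNA also set genes apart mostly downwards, with 90% of 20 such genes lower (75.6% of 217 with an intensity trend), so a candidate explanation is that part of the risers are transcripts that the scramble siRNA itself lowered. Simulated unchanged groups gave at most 0 shared calls but draw only on limma's moderated estimate of the spread between duplicates. Noise in the shared scramble arrays therefore cannot be told apart from the other explanations where both arrays carry the same deviation. A rise in proportion to PPP2R2A depletion would be 1.34 times as large with siRNA 1 on the log2 scale (interval 1.11 to 1.67), and siRNA 1 minus that multiple of siRNA 2 was -0.42 over the risers (interval -0.84 to -0.10), but the risers had to pass the threshold with both siRNAs, which favours changes of equal size, so PPP2R2A loss cannot be told apart from lowering by the scramble siRNA, as no untransfected group was measured.

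The interferon list was higher with siRNA 1 than with siRNA 2 by camera (adjusted p = 3.28e-05, and adjusted p = 0.509 with an estimated correlation). Both siRNA 1 arrays showed it, the lower at a median of 0.39 and the higher at 0.52, which argues against a single array. Between the siRNA 2 duplicates the list differed by -0.0308 (interval -0.11 to 0.03) against 0.21 between the siRNAs, so 3' bias cannot be told apart from the other explanations of part of the difference, since that interval holds both 0 and a fall of a size that matters beside 0.21. Scaling siRNA 2 by the ratio of PPP2R2A depletion left a difference of 0.20 with an interval from -0.09 to 0.39. As the interval includes 0, the list median cannot tell PPP2R2A loss in proportion apart from a response to the siRNA 1 molecule. Strict proportion would also keep each member's sign. With siRNA 2, 17 of 42 members lay below 0 and 3 fell adjusted over the list alone. With siRNA 1 these counts were 1 and 0. That argues against strict proportion for the members that fell with siRNA 2, while 25 members lay above 0 with both siRNAs.

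The unfolded protein response and ATF4 targets were higher with both siRNAs (adjusted p = 0.419 and 0.333 with an estimated correlation). Against single scramble arrays the lowest list median was 0.25, so no single scramble array accounts for the rise. Between the siRNA 2 duplicates the list differed by 0.0558 (interval 0.02 to 0.09) against a change of 0.40, which argues against 3' bias as the whole cause. Scaling siRNA 2 by the ratio of PPP2R2A depletion left -0.30 (interval -0.46 to -0.05). That argues against a rise in strict proportion to depletion as read on probe set 202313_at. On 228013_at the PPP2R2A log2 changes were closer to each other, -2.30 with siRNA 1 and -2.01 with siRNA 2. Scaling by that probe set was not tested, so strict proportion to its reading stays open. A response to PPP2R2A loss of another form, and a response to each active siRNA molecule, were not tested and stay open.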

How the results depend on the processing

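The fits that combine an intensity trend with leaving out an array were chosen only after the result was seen. Counts are given in the order siRNA 1, siRNA 2, difference between the siRNAs, and both siRNAs, which stood at 50, 76, 27 and 20 genes. Quantile normalization gave 33, 71, 12 and 14, and centring each array on its median 11, 1, 0 and 1. An intensity trend gave 299, 472, 362 and 121, and a filter at the 75th percentile 280, 389, 323 and 114. Without a filter, or with the mean of a gene's probe sets, all counts were 0, and all probe sets gave 0, 1, 0 and 0. Only the 4 arrays compared gave 0, 0 and 0. A 2-fold limit gave 48 with siRNA 2, and a pseudocount of 16 gave 162 with siRNA 2 and 31 with both. With duplicates averaged and 1 residual degree of freedom 0 genes were called with both (725 at an unadjusted p under 0.05, smallest adjusted p 0.727). Leaving out each array in turn gave 0 to 0 for every count. The lone array left in a group was assumed to vary like the other groups. With an intensity trend the same leave-outs gave 227 to 285, 329 to 451, 253 to 360 and 98 to 113 calls, keeping 44 to 46 of 50, 66 to 71 of 76, 22 to 23 of 27 and 18 to 19 of 20. Where limma called 0, genes at an unadjusted p under 0.05 numbered 1371 to 3285, 1729 to 2526, 1495 to 3882 and 565 to 1359. Every called gene lay close to the adjusted p threshold of 0.05. With siRNA 1 the adjusted p by limma ran from 0.0368 to 0.0498, and with siRNA 2 from 0.0385 to 0.0492. In the difference between the siRNAs it ran from 0.0418 to 0.04998. Small changes in the fit can therefore remove many calls together. Fewer arrays leave fewer degrees of freedom, but the fits without a filter and with the mean of probe sets kept every array. What else caused these shifts was not tested.

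PPP2R2A stayed lower in every alternative, but its mean change was no longer called without the filter (-1.76, adjusted p = 0.180), with the mean of its probe sets (-1.25, adjusted p = 0.109), over all probe sets (-1.76, adjusted p = 0.0749), or without single arrays (-1.86 to -1.66, adjusted p from 0.129 to 0.200). In the fit over all probe sets without a filter its other probe sets gave -2.16 (228013_at), -0.21 (236492_at) and -0.89 (237636_at), with adjusted p from 0.273 to 0.839. The correlation between the siRNAs lay between 0.402 and 0.634 without single arrays, and at 0.109 and 0.146 with split scramble arrays, which removes by construction the shared noise of single arrays, but no deviation common to both. Lists called with both siRNAs numbered 1 with quantile normalization, without a filter, at the 75th percentile and with the mean of probe sets (basal and squamous genes being lost), 3 with an intensity trend, 0 with an estimated correlation, and 1 to 2 without single arrays. CCND3 reversed with the mean of its probe sets, to -0.12 with siRNA 1 and -0.0778 with siRNA 2. No other CCND3 probe set was above the filter, so the reversal came from probe sets below it. Of 986 values for called single genes under an alternative, 323 stayed called, 661 lost the call in the same direction and 2 reversed. Of 208 for called list medians 171 stayed called and 37 did not. Among values not called, 97 of 1805 for genes and 16 of 1298 for lists became called. The interferon list with siRNA 1 (medians 0.39 to 0.54) and the unfolded protein response and ATF4 list with siRNA 1 (0.25 to 0.34) and siRNA 2 (0.37 to 0.44) stayed called in each of 13 alternatives that kept the preset correlation. Signal near background limits genes with a dim group such as ALPP, LRIG1, ADAMTS10 and CIB2, whose folds depend on the background level.

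The letters A and B share no stated origin. As a pairing check, deviations of same-lettered arrays correlated at -0.03, 0.01 and 0.04 between groups, so no strong pairing by letter was seen. Correlations over all tested genes cannot exclude that same-lettered arrays were handled together. With the letter as a block the counts were 0, 0, 0 and 0 (1921, 2485, 2235 and 855 at an unadjusted p under 0.05), and PPP2R2A stood at -1.76 with an adjusted p = 0.143.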

Other observations

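Apart from the fixed lists, the genes and branches in this part were chosen only after the result was seen. The endoplasmic reticulum and amino acid branches of the stress list both lay above 0. Over 16 chaperone and degradation genes the median log2 change was 0.41 with siRNA 1 and 0.29 with siRNA 2, and over 21 ATF4 and amino acid genes it was 0.22 and 0.46. DDIT3, the stress-induced transcription factor also known as CHOP, stood at 0.87 and 1.11, and was called with an intensity trend (adjusted p = 0.0242 and 0.00452). The interferon-stimulated genes XAF1 (1.51 and 1.48), IFITM1 (1.02 and 1.15) and IFI27 (0.95 and 1.06) were also called with both siRNAs in that fit. So were the integrin gene ITGB8 (1.60 and 1.23) and, as falls, ID3, an inhibitor of DNA binding (-1.07 and -0.95), and SERPINB3, a squamous epithelial serpin (-0.91 and -0.89). None of these genes was called with both siRNAs under the constant prior.

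The other lists, called with neither siRNA, had these median log2 changes with siRNA 1 and siRNA 2. In signalling, targets of ERK lay at -0.04 and -0.05 with HMGA2 called, FGFR, EGFR and RAS components at 0.01 and 0.01 with MET called, the Notch pathway at -0.08 and -0.01 with the gamma-secretase subunit APH1A called lower with siRNA 1 (-0.92) and in the difference (-1.11), PI3K and FOXO targets at 0.02 and 0.13 with TRIB3 called, Wnt at 0.07 and 0.00, and YAP and TEAD targets at -0.04 and 0.02 with PTPN14 called. Of the actin and SRF targets, a list called with siRNA 1, CALD1 was called higher with siRNA 2 (0.85). In metabolism, cholesterol synthesis lay at -0.04 and 0.10, fatty acid synthesis at 0.06 and -0.08, hypoxia and glycolysis at -0.02 and -0.08, and oxidative phosphorylation at -0.06 and -0.03. Proteasome genes lay at 0.05 and 0.04, heat shock genes at -0.04 and -0.03, NRF2 targets at 0.12 and -0.10 (called with both in opposite directions with an intensity trend), and autophagy and lysosome genes at 0.09 and 0.12. Apoptosis regulators lay at 0.05 and -0.02 with MCL1 called, epithelial junctions at 0.07 and -0.06 with CLDN1 called, epithelial-mesenchymal transition genes at 0.12 and -0.05, chromatin modifiers at 0.09 and 0.11, the RNA interference machinery at 0.08 and 0.02, and other protein phosphatase subunits at -0.04 and -0.01. Housekeeping genes had medians of -0.02 and -0.07. Markers of other cell types did not rise as lists: fibroblast markers (7 tested) lay at 0.10 and 0.15, leukocyte markers (6 tested) at -0.26 and -0.31, and neural markers (5 tested) at 0.15 and 0.15, none called by camera. Of the endothelial markers 3 passed the filter, too few to test, with a median of -0.05 and -0.31.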
